A study of Mus musculus with 24 samples.

How the data were processed

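RNA was measured by bulk sequencing of 24 kidney samples: 6 wild-type and 6 proximal tubule-specific Lrp2 knockout libraries after 2 weeks of Western diet, and 6 of each after 12 weeks. Per the labels, RNA was purified with the Maxwell RSC simplyRNA kit and libraries were made with a NEBNext Ultra RNA kit; the strand handling is not stated. The labels also call the mice LRP2-SM22 without explaining the name, so the proximal tubule specificity of the knockout rests on the series record. The deposited files hold raw read counts per Ensembl gene, 1 library per file, without normalization. The submitters name fastp, STAR 2.5 and HTSeq 0.6.1 and the mouse build mm10; their options, the strand setting of the counting and the annotation release are not given in the sources used here. Of 54532 gene identifiers, 54495 matched GENCODE M21, which was used for symbols, positions and overlaps, and the 37 others held at most 0.00528% of the counts of a library. The files held no lines for unassigned reads.

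Total counts per library, in megacounts (M), were 21 ± 6.7 M (mean ± SD) in wild type and 19.3 ± 3.3 M in knockout at 2 weeks, and 12.3 ± 1.2 and 13.3 ± 1.4 M at 12 weeks. Where a group had 0 counts for a gene, the fold change is a bound against 3 counts over the summed libraries of that group. Intervals and floors of this kind cover counting error only, since reads copied by PCR are not independent molecules. The 10 genes with the most counts took 13.4% ± 0.9, 11.3% ± 1.9, 19.2% ± 0.8 and 14.9% ± 1.3 of the counts in wild type and knockout at 2 weeks and wild type and knockout at 12 weeks. The predicted gene Gm42418, named outside the rule, had 0 counts in all libraries at 2 weeks. At 12 weeks it had 86843 to 401812 counts per wild-type library and 71635 to 424892 per knockout library. Its part in the higher share at 12 weeks was not tested.

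The groups, comparisons, tests, gene lists, the rule for naming genes and all alternatives, save those given as added, were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood F test, two-sided, Benjamini-Hochberg adjusted p under 0.05). filterByExpr (minimum count 10, minimum total 15) over the 24 libraries kept 17286 genes. Each genotype comparison was fitted on the 12 libraries of its duration; the interaction and the duration comparisons were fitted on all 24. The standard error of a log2 fold change was its absolute value over the square root of F. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated per list and with fry. Of 40 lists 38 were tested; the adrenal cortex list had 2 tested members and the list of sex-chromosome transcripts 4. The lists hold 790 entries, of which 789 matched a gene. Replicate numbers do not pair the libraries: the correlation of residuals between libraries of equal number lay between -0.28 and 0.17.

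The named genes are Lrp2 and those given by the rule below. For each genotype comparison the rule took the 8 called genes with the largest log2 fold change in each direction. Eligible genes had a mean of at least 1 CPM, no overlap of the groups and a symbol that is not a predicted gene. The same conditions gave 4 per direction for duration. For the interaction 5 per direction were taken without the condition on overlap. Up to 4 called members of each list with the smallest adjusted p were added, named in that order. Genes named outside the rule are given as such. Some genes that the rule names are not reported here.

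Simulated data held 100 genes changed by a log2 fold change of 1 and 100 changed by 2, with as many up as down. The 2-week comparison found 81 and 99 of these, with 8 false calls over both sizes. The 12-week comparison found 73 and 97 with 7 false calls, and the interaction 66 and 90 with 13. The simulation drew genes independently and changed far fewer genes than the genotype comparisons called, so these rates may not carry over to the real data. No pair of libraries was close enough to be a duplicate. Alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter, a mean of at least 1 CPM, an added minimum log2 fold change of 1, a replicate block, all 24 libraries in 1 fit, removal of sex-chromosome and immunoglobulin or T cell receptor segment genes, and each library left out in turn. Removal of genes that overlap a gene on the opposite strand, and leaving out libraries for the shared calls and the correlation of fold changes, were added after seeing the data. Figures were drawn with Python 3.11.15.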

Results

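Gene expression was measured by bulk RNA sequencing in 24 kidney samples of mice fed a Western diet, a fat-rich rodent feed whose composition is not given in the sources used here. The mice either lacked Lrp2 in proximal tubule cells or were wild-type littermates, and kidneys were taken after 2 or 12 weeks of diet, with 6 libraries in each of the 4 groups. Lrp2 encodes megalin, the large endocytic receptor of the proximal tubule brush border that takes up filtered proteins. The series title names tubulointerstitial nephritis, so the question was how the kidney transcriptome of the knockout differed from wild type at each duration and whether that difference depended on duration. Total counts per library, in megacounts (M), ranged from 15.6 to 34.1 M in wild type and 16.3 to 25.2 M in knockout at 2 weeks. At 12 weeks they ranged from 11.4 to 14.5 M in wild type and 11.3 to 15.2 M in knockout. Levels are in CPM, read counts per megacount of the TMM-scaled library, given as mean ± SD over 6 libraries, and each log2 fold change carries its standard error (SE). The labels do not state that each library came from a separate mouse, so p-values measure only the spread between these samples.

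Lrp2 RNA was lower in every knockout library than in every wild-type library at both durations. At 2 weeks the wild-type libraries held 1590, 1910, 2180, 1880, 2190 and 2290 CPM of Lrp2 in replicates 1 to 6, and the knockout libraries held 232, 584, 192, 318, 356 and 432 CPM. At 12 weeks the wild-type values of Lrp2 were 1410, 1730, 1690, 1810, 2120 and 2500 CPM and the knockout values 356, 186, 390, 330, 307 and 368 CPM. The knockout mean of Lrp2 was 17.6% of wild type at 2 weeks (352 ± 142 against 2000 ± 261 CPM, log2 fold change -2.49, SE 0.23, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 2.4e-06). It was 17.2% at 12 weeks (323 ± 73.1 against 1880 ± 382 CPM, log2 fold change -2.51, SE 0.18, edgeR adjusted p = 3.9e-07). Lrp2 (chromosome 2, 69424340 to 69586065, minus strand, mm10) has no annotated overlap with a gene on the opposite strand, and the position of the deleted exons is not given in the sources used here.

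**Figure D1:**
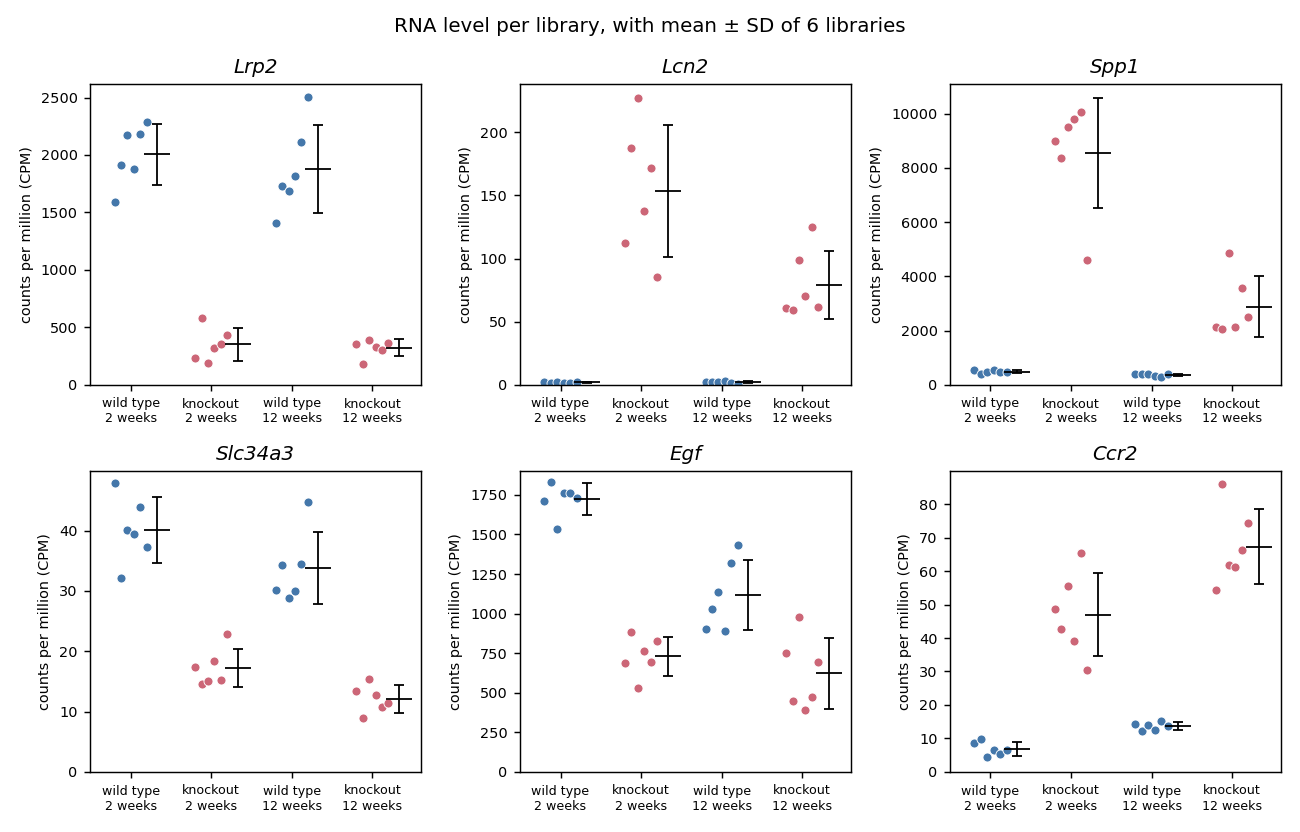
CPM (vertical axis) of Lrp2, Lcn2, Spp1, Slc34a3, Egf and Ccr2 in each library (points) by genotype and diet duration (horizontal axis), with the mean ± SD of 6 libraries as a bar beside each group. The lowest wild-type Lrp2 value is 1410 CPM and the highest knockout value 584 CPM.

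After 2 weeks of diet, knockout kidneys held more RNA of tubular injury genes, chemokines, leukocyte markers and matrix genes than wild-type kidneys. They held less RNA of proximal tubule transporters, mitochondrial enzymes, and markers of the thick ascending limb, distal convoluted tubule and intercalated cells. Lcn2, which encodes the secreted tubular injury marker lipocalin 2, rose 80.2-fold, from 1.92 ± 0.596 to 154 ± 51.9 CPM (log2 fold change 6.33, SE 0.31, edgeR adjusted p = 3.9e-08). Spp1, the gene for osteopontin, rose 17.7-fold, from 492 ± 60.8 to 8550 ± 2040 CPM (log2 fold change 4.15, SE 0.18, edgeR adjusted p = 7.1e-11). Egf, the epidermal growth factor gene of the distal nephron, fell to 0.431 of the wild-type level, from 1720 ± 101 to 730 ± 124 CPM (log2 fold change -1.21, SE 0.10, edgeR adjusted p = 9.9e-08). The sodium-phosphate cotransporter gene Slc34a3 fell to 0.437 of wild type, from 40.1 ± 5.46 to 17.2 ± 3.11 CPM (log2 fold change -1.19, SE 0.11, edgeR adjusted p = 3.3e-07). In all, 5467 of 17286 tested genes (31.6%) passed, 3144 higher and 2323 lower in knockout (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Of these, 1429 higher and 191 lower genes differed by a log2 fold change of at least 1. The values of the 2 groups did not overlap for 2868 genes (16.6%), against a chance share of 0.216%.

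At 2 weeks Sprr2f, a small proline-rich protein of stressed epithelia, had 0 counts in all 6 wild-type libraries and 3.19 ± 0.783 CPM in knockout, at least 134-fold higher against a floor of 3 counts over the summed wild-type libraries. Cxcl5, a chemokine that attracts neutrophils, rose 257-fold, from 0.04 ± 0.0504 to 9.55 ± 4.69 CPM (log2 fold change 8.01, SE 0.57, edgeR adjusted p = 9.6e-08). The matrix metalloproteinase gene Mmp7 rose 152-fold to 7.93 ± 4.46 CPM and the chemokine gene Cxcl2 136-fold to 5.08 ± 1.03 CPM (edgeR adjusted p = 6.2e-08 and 2.5e-09). The interleukin 1 family gene Il1f6 rose 99.0-fold to 5.84 ± 1.84 CPM, and Timp1, an inhibitor of matrix metalloproteinases, 92.8-fold to 27.4 ± 12.9 CPM (edgeR adjusted p = 3.1e-09 and 1.3e-06). Saa1, an acute-phase protein gene, stood at 2.31 ± 0.689 CPM in knockout and 0.00463 ± 0.0113 CPM in wild type, where 1 count was found in all. Among the genes that fell most, Ctxn3 dropped to 0.132 of wild type (9.03 ± 2.15 to 1.15 ± 0.477 CPM, log2 fold change -2.92, SE 0.24, edgeR adjusted p = 5.2e-08). Cntnap5a fell to 0.221, the Wnt ligand gene Wnt11 to 0.242, Coch to 0.249, Nepn to 0.284, Perm1 to 0.331 and Col19a1 to 0.334 of wild type (edgeR adjusted p between 1.8e-07 for Perm1 and 0.0044 for Col19a1). Timp1 and Ctxn3 lie within annotated genes on the opposite strand, and Mmp7, Wnt11 and Egf overlap such genes in part; the strand setting of the counting is not given in the sources used here, so their values are uncertain. With few wild-type counts, 1 library moved some values by over 1.5-fold: the log2 fold change of Cxcl5 was 8.66 without wild-type replicate 6, that of Cxcl2 7.71 and 7.75 without wild-type replicates 4 and 6 (7.09 with all), and that of Il1f6 7.25 without wild-type replicate 1 (6.63 with all). Sprr2f, Saa1 and Cxcl5 have close paralogs with which reads could be shared.

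All 27 tested members of the list of proximal tubule injury genes rose at 2 weeks, as did all 27 adjusted over the list alone, with a median log2 fold change of 2.77, also with Sprr2f set at its bound. The limma camera test gave adjusted p = 6.4e-27, and adjusted p = 0.0268 with an estimated correlation, the sole list call that held with it. Besides Spp1, the fibrinogen beta chain gene Fgb rose 35.1-fold, from 0.878 ± 0.28 to 30.1 ± 7.8 CPM (log2 fold change 5.13, SE 0.22, edgeR adjusted p = 4.5e-10). Of 27 transporter genes of the proximal tubule 22 fell and 1 rose, 23 and 1 adjusted over the list alone (median -0.48, camera adjusted p = 3.03e-08, adjusted p = 0.205 with an estimated correlation). The riser was Slc13a1, the sodium-sulfate cotransporter gene, which rose 2.96-fold from 228 ± 36.7 to 662 ± 102 CPM (log2 fold change 1.56, SE 0.12, edgeR adjusted p = 3.2e-08). In the list for the S3 segment, the last part of the proximal tubule, 8 of 12 genes fell and none rose, 9 adjusted over the list alone (median -0.52, camera adjusted p = 0.00011, adjusted p = 0.216 with an estimated correlation). Slc22a13, an organic anion transporter gene of that list, fell to 0.575 of wild type (52.6 ± 7.63 to 29.6 ± 3.27 CPM, edgeR adjusted p = 6.1e-06), and Acy3 to 0.674 (edgeR adjusted p = 0.0017).

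Immune genes rose together at 2 weeks. All 27 macrophage and dendritic cell genes rose, 27 adjusted over the list alone (median log2 fold change 2.17, camera adjusted p = 2.31e-22, adjusted p = 0.116 with an estimated correlation). Cd74, the invariant chain of antigen presentation, rose 4.56-fold from 202 ± 19.4 to 904 ± 197 CPM and the class II gene H2-Ab1 4.46-fold from 83.4 ± 8.98 to 365 ± 90.4 CPM (edgeR adjusted p = 3.1e-09 and 2.5e-08). Among 33 cytokine and chemokine genes 28 rose and none fell, with the same 28 and 0 adjusted over the list alone (median 1.89, camera adjusted p = 2.1e-19, adjusted p = 0.0592 with an estimated correlation). Next to Cxcl2, the monocyte chemoattractant gene Ccl2 rose 14.4-fold to 6.64 ± 2.04 CPM (edgeR adjusted p = 3.4e-09), though Ccl2 lies within a gene on the opposite strand and is uncertain. For T and natural killer cells 15 of 20 genes rose, 15 adjusted over the list alone (median 1.34, camera adjusted p = 3.21e-07, adjusted p = 0.116 with an estimated correlation). Ccl5 was 3.97-fold higher (0.989 ± 0.369 to 3.9 ± 0.943 CPM). All 8 neutrophil genes rose, 8 adjusted over the list alone (median 1.96, camera adjusted p = 1.78e-05, adjusted p = 0.116 with an estimated correlation). Csf3r was 4.30-fold higher (1.97 ± 0.397 to 8.42 ± 1.58 CPM). Of 22 B and plasma cell genes 10 rose and 1, the complement receptor gene Cr2, fell (14 and 1 adjusted over the list alone, median 1.14, camera adjusted p = 0.00164, adjusted p = 0.282 with an estimated correlation). Ighm, the immunoglobulin mu heavy chain gene, rose 2.78-fold from 5.55 ± 1.7 to 15.3 ± 2.58 CPM (edgeR adjusted p = 3.8e-06), a call that ended in a fit of all 24 libraries (log2 fold change 1.44, edgeR adjusted p = 0.347). In the complement list 17 of 21 genes rose and C4a fell, 17 and 1 adjusted over the list alone (median 1.71, camera adjusted p = 1.14e-11, adjusted p = 0.116 with an estimated correlation). C4b rose 19.1-fold to 96.5 ± 18.7 CPM and Cfi, which encodes complement factor I, 20.4-fold to 41.5 ± 9.71 CPM (edgeR adjusted p = 7.1e-11 and 5.9e-10). Interferon response genes rose in 32 of 36 cases with none lower, 33 higher and 1 lower adjusted over the list alone (median 1.05, camera adjusted p = 5.64e-15, adjusted p = 0.137 with an estimated correlation). In that list the class II transactivator gene Ciita rose 2.86-fold to 19.7 ± 2.26 CPM (edgeR adjusted p = 5.6e-08); most of its length lies opposite another gene, so the value is uncertain.

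Matrix, cell cycle, and immediate early and heat shock genes were also higher at 2 weeks. Of 40 fibroblast and extracellular matrix genes 37 rose and none fell, 38 adjusted over the list alone (median log2 fold change 1.37, camera adjusted p = 5.15e-21, adjusted p = 0.116 with an estimated correlation). After Mmp7, Tgfbi, an extracellular protein induced by transforming growth factor beta, rose 4.59-fold from 9.89 ± 1.8 to 44.5 ± 10.4 CPM (edgeR adjusted p = 6.7e-08). Cell cycle genes rose in 27 of 30 cases and Ccnd1 fell, 27 and 1 adjusted over the list alone (median 1.44, camera adjusted p = 1.56e-13, adjusted p = 0.116 with an estimated correlation). Cenpf, a mitotic kinetochore gene, was 4.14-fold higher at 5.97 ± 1.44 CPM. In the list of transforming growth factor beta and Wnt signalling 12 of 24 genes rose and 4 fell, 12 and 5 adjusted over the list alone (median 0.29, camera adjusted p = 0.0152, adjusted p = 0.339 with an estimated correlation). That list lost its call without genes that overlap the opposite strand (camera adjusted p = 0.146). Immediate early and heat shock genes rose in 9 of 18 cases and Dusp1 fell, 9 and 1 adjusted over the list alone (median 0.63, camera adjusted p = 0.00327, adjusted p = 0.116 with an estimated correlation). Atf3, a stress-induced transcription factor gene, rose 6.83-fold from 1.36 ± 0.401 to 9.32 ± 1.01 CPM (edgeR adjusted p = 4.2e-09).

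Genes of several distal nephron segments, of mitochondria, fatty acid oxidation and lipogenesis were lower at 2 weeks. The lists of principal cells and of sterol synthesis did not pass (camera adjusted p = 0.122 and 0.493). In the intercalated cell list 10 of 11 genes fell, 10 adjusted over the list alone (median log2 fold change -0.47, camera adjusted p = 1.19e-06, adjusted p = 0.116 with an estimated correlation). Slc4a1, the basolateral anion exchanger gene of intercalated cells and red cells, fell to 0.455 of wild type (56.1 ± 5.42 to 25.1 ± 2.87 CPM, edgeR adjusted p = 2.1e-08), and Insrr to 0.428 (68.7 ± 9.77 to 29 ± 5.43 CPM, uncertain because it lies within a gene on the opposite strand). Distal convoluted and connecting tubule genes fell in 8 of 10 cases, 10 adjusted over the list alone (median -0.44, camera adjusted p = 1.78e-05, adjusted p = 0.116 with an estimated correlation). Pvalb stood at 0.392 of wild type (31 ± 4.49 to 11.9 ± 2.37 CPM). In the thick ascending limb list, which holds Egf, 4 of 10 genes fell, 5 adjusted over the list alone (median -0.29, camera adjusted p = 0.00889, adjusted p = 0.205 with an estimated correlation). Without genes that overlap the opposite strand 4 members were left, too few for the test. Of 30 respiratory chain genes 22 fell, 27 adjusted over the list alone (median -0.30, camera adjusted p = 8.6e-11, adjusted p = 0.116 with an estimated correlation). Sdhc, a subunit of succinate dehydrogenase, fell to 0.750 of wild type (320 ± 17.9 to 235 ± 17.5 CPM, edgeR adjusted p = 0.00025). Transcripts of the mitochondrial genome fell in 9 of 13 cases, 11 adjusted over the list alone (median -0.57, camera adjusted p = 3.83e-05, adjusted p = 0.272 with an estimated correlation). mt-Co2 stood at 0.621 of wild type. Counts on mitochondrially encoded genes took 8.9% ± 0.6 of the wild-type and 6.9% ± 1.6 of the knockout libraries. Fatty acid oxidation genes fell in 19 of 31 cases and Angptl4 rose, 20 and 1 adjusted over the list alone (median -0.34, camera adjusted p = 1.18e-06, adjusted p = 0.116 with an estimated correlation). The thiolase gene Acaa2 stood at 0.604 of wild type (164 ± 14.9 to 97.2 ± 10.4 CPM). In the lipogenesis list 8 of 18 genes fell while Elovl6 and Fads1 rose, 9 and 2 adjusted over the list alone (median -0.38, camera adjusted p = 0.0176, adjusted p = 0.384 with an estimated correlation), and Acss2 stood at 0.697 of wild type, uncertain for its overlap with another gene.

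In all, 21 of 38 tested lists passed the camera test at 2 weeks, 12 higher and 9 lower. Other splits of the same 12 libraries into 6 and 6 gave a median of 14 and up to 27 lists, so chance cannot be excluded for this number. A camera adjusted p at the preset correlation is therefore weak evidence by itself for a single list. The counts of single genes in each list are to be read against the 31.6% of all tested genes called at 2 weeks. The thick ascending limb list, with 4 of 10 genes called, lies near that share. The fold changes of members shared between lists, such as Timp1, Ccl2 and Slc4a1, enter more than 1 list. Members of minority direction (Cr2, C4a, Ccnd1, Dusp1, Elovl6, Fads1) were named after their values were seen.

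**Figure D2:**
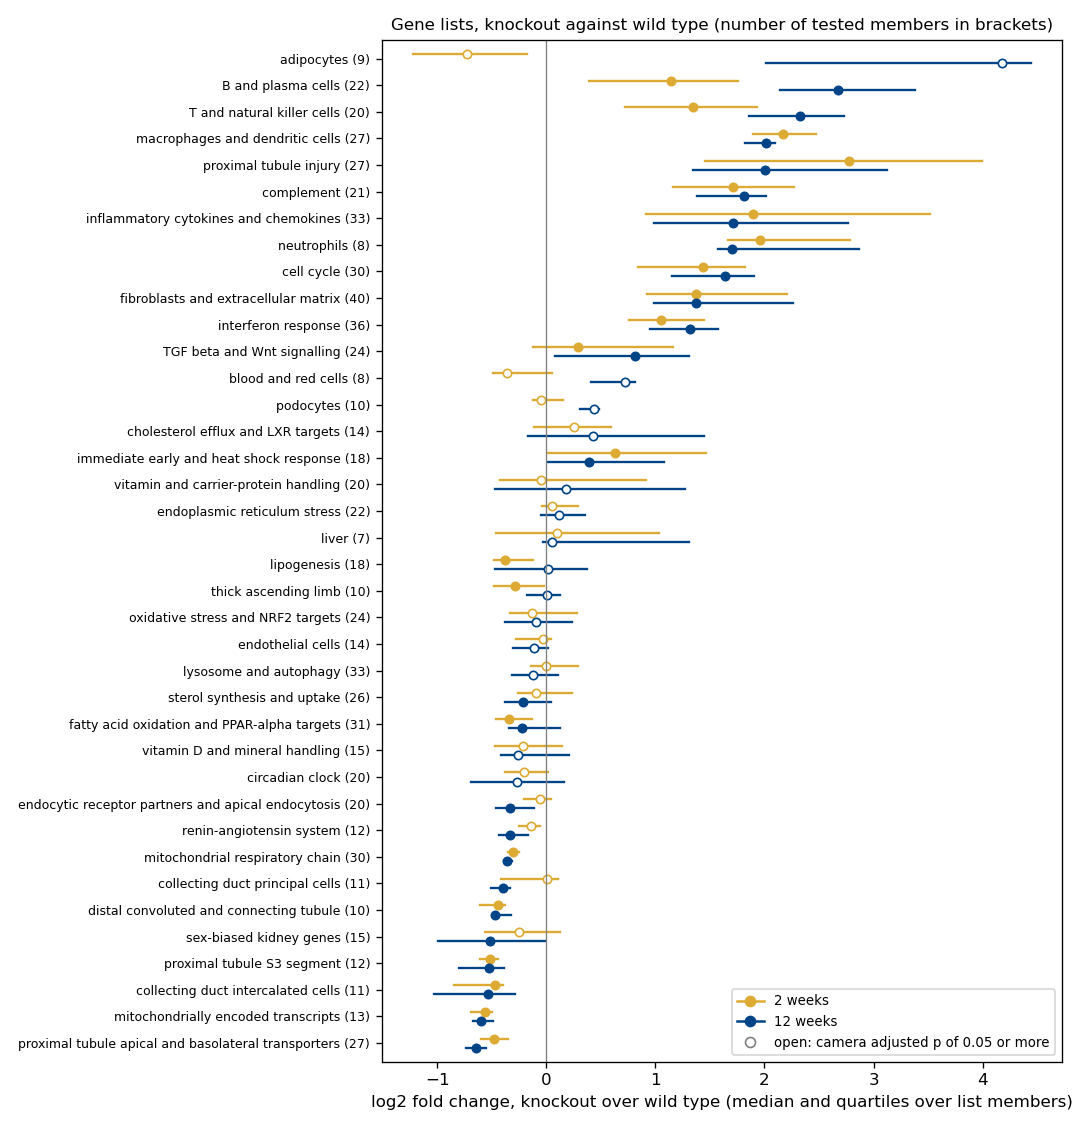
Median log2 fold change, knockout over wild type (horizontal axis), with the range between quartiles as a line, for the members of each tested gene list (vertical axis, number of tested members in brackets) at 2 weeks (yellow) and 12 weeks (blue). Filled points mark lists with a camera adjusted p under 0.05 at the preset correlation; the injury list lies at 2.77 and 2.00 and the transporter list at -0.48 and -0.65.

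After 12 weeks of diet, the genes higher in knockout kidneys again included injury, immune and matrix genes, and transporter, mitochondrial, distal convoluted tubule and intercalated cell genes were again lower. The thick ascending limb list, lower at 2 weeks, did not pass. Lcn2 was 40.9-fold higher, at 79.3 ± 26.9 against 1.98 ± 0.848 CPM (log2 fold change 5.35, SE 0.31, edgeR adjusted p = 5.4e-07). Gabrp, an epithelial GABA receptor subunit gene, rose 98.8-fold from 0.0645 ± 0.0794 to 7.03 ± 4.84 CPM (log2 fold change 6.63, SE 0.76, edgeR adjusted p = 3.7e-05); without wild-type replicate 1, on few counts, the log2 fold change of Gabrp was 7.25. The calcitriol-degrading enzyme gene Cyp24a1 fell to 0.106 of wild type, from 116 ± 51.7 to 12.1 ± 3.75 CPM (log2 fold change -3.24, SE 0.33, edgeR adjusted p = 3.9e-05). Slc34a3 fell to 0.365 of wild type, from 33.8 ± 5.91 to 12.1 ± 2.25 CPM (log2 fold change -1.46, SE 0.13, edgeR adjusted p = 2.3e-06). The test called 6653 of 17286 genes (38.5%), 3585 higher and 3068 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), of which 1812 and 181 had a log2 fold change of at least 1. For 3176 genes (18.4%) the groups did not overlap, against a chance share of 0.216%. Without genes that overlap the opposite strand 4420 of 10983 genes were called.

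At 12 weeks the mucin gene Muc4 rose 69.6-fold to 7.05 ± 2.67 CPM, the immunoglobulin variable segment Ighv1-26 58.3-fold to 14.1 ± 22.1 CPM, Lgi2 55.6-fold to 12.5 ± 5.1 CPM and Cxcl5 44.6-fold to 7.3 ± 1.75 CPM (edgeR adjusted p = 2.1e-06, 0.0036, 2.9e-06 and 1e-05). Knockout replicate 2 held 58 CPM of Ighv1-26 and the others 1.64 to 15.3 CPM; without it the log2 fold change was 4.48 in place of 5.87 (edgeR adjusted p = 0.000372). Foxp3, the transcription factor of regulatory T cells, rose 39.7-fold from 0.124 ± 0.16 to 5.26 ± 4.03 CPM (log2 fold change 5.31, SE 0.69, edgeR adjusted p = 9e-05). Few wild-type counts left these folds open to 1 library: without wild-type replicate 1 the log2 fold change was 6.78 for Muc4 (6.12 with all), 6.51 for Lgi2 (5.80) and 6.18 for Cxcl5 (5.48). Without wild-type replicate 2 it was 6.75 for Muc4 and 5.96 for Foxp3, and without wild-type replicate 3 it was 6.18 for Cxcl5. Il1f6 stood at 3.19 ± 1.33 CPM in knockout and 0.0459 ± 0.0754 CPM in wild type, where too few counts were found for a fold change. Saa1 had 0 counts in wild type and 1.77 ± 1.11 CPM in knockout, at least 37.9-fold higher. Among the genes that fell, the coagulation factor V gene F5 stood at 0.232, Nepn at 0.235, Ctxn3 at 0.237, Tldc2 at 0.257, the histidine-rich glycoprotein gene Hrg at 0.269 and Col19a1 at 0.278 of wild type (edgeR adjusted p between 2.2e-05 for Nepn and 0.00046 for Ctxn3). Foxp3 and Ctxn3 lie within genes on the opposite strand, Muc4, Cyp24a1 and F5 overlap such genes in part, and Ighv1-26 shares sequence with other segments, so these values are uncertain.

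All 27 injury genes rose at 12 weeks, 27 adjusted over the list alone (median log2 fold change 2.00, camera adjusted p = 2.36e-18, adjusted p = 0.144 with an estimated correlation). Dcdc2a rose 3.17-fold to 73.3 ± 10.4 CPM, the keratin gene Krt18 3.53-fold to 34.2 ± 5.47 CPM and Spp1 8.01-fold to 2880 ± 1120 CPM (edgeR adjusted p = 3.2e-07, 3.6e-07 and 4.8e-07). Of 27 proximal tubule transporter genes 24 fell and Slc13a1 rose, 24 and 1 adjusted over the list alone (median -0.65, camera adjusted p = 3.4e-10, adjusted p = 0.331 with an estimated correlation). The organic cation transporter gene Slc22a2 fell to 0.648 of wild type (305 ± 24.3 to 194 ± 26.9 CPM, edgeR adjusted p = 0.00016). S3 segment genes fell in 7 of 12 cases, 8 adjusted over the list alone (median -0.53, camera adjusted p = 2.77e-05, adjusted p = 0.331 with an estimated correlation). Acy3 stood at 0.546 of wild type (1930 ± 212 to 1030 ± 135 CPM, edgeR adjusted p = 3.6e-05). Among 20 genes of endocytic receptor partners and apical endocytosis 11 fell and Gipc1 rose, 13 and 1 adjusted over the list alone (median -0.33, camera adjusted p = 0.000544, adjusted p = 0.331 with an estimated correlation). Amn, which encodes the membrane anchor of the cubilin receptor, fell to 0.672 (121 ± 7.14 to 79.9 ± 13 CPM) and the endocytic adaptor gene Dab2 to 0.687 (470 ± 73.4 to 316 ± 37.6 CPM) of wild type (edgeR adjusted p = 0.00039 and 0.0013). In the renin-angiotensin list 4 of 12 genes fell and Agt rose, 4 and 1 adjusted over the list alone (median -0.34, camera adjusted p = 0.0261, adjusted p = 0.331 with an estimated correlation). The angiotensin receptor gene Agtr1a stood at 0.726 and Ace at 0.624 of wild type. That list lost its call without genes that overlap the opposite strand (camera adjusted p = 0.119), Ace being among those.

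Leukocyte lists rose at 12 weeks too. Macrophage and dendritic cell genes rose in 26 of 27 cases, 26 adjusted over the list alone (median log2 fold change 2.01, camera adjusted p = 2.48e-16, adjusted p = 0.331 with an estimated correlation). Ccr2, the chemokine receptor of inflammatory monocytes, rose 5.02-fold from 13.7 ± 1.15 to 67.3 ± 11.2 CPM (edgeR adjusted p = 5.8e-09), and H2-Ab1 4.03-fold to 467 ± 107 CPM. For T and natural killer cells 18 of 20 genes rose, 18 adjusted over the list alone (median 2.33, camera adjusted p = 2.06e-08, adjusted p = 0.331 with an estimated correlation). The interleukin 7 receptor gene Il7r was 7.54-fold higher (1.27 ± 0.598 to 9.46 ± 5.12 CPM). Of 22 B and plasma cell genes 13 rose and none fell, 16 adjusted over the list alone (median 2.68, camera adjusted p = 0.000762, adjusted p = 0.541 with an estimated correlation). The immunoglobulin alpha heavy chain gene Igha rose 6.65-fold from 100 ± 47.9 to 657 ± 531 CPM (edgeR adjusted p = 0.0035). Knockout replicate 2 held 4310 CPM of Ighm against 34.2 to 424 CPM in the other 5 knockout libraries; without it, 8 of 22 B and plasma cell genes rose and the list median was 1.66 (camera adjusted p = 0.00243). Cytokine and chemokine genes rose in 26 of 33 cases and Ccl28 fell, 28 and 1 adjusted over the list alone (median 1.72, camera adjusted p = 9.3e-14, adjusted p = 0.331 with an estimated correlation). Icam1, which overlaps an opposite-strand gene in part, was 2.45-fold higher (25.6 ± 2.29 to 61.5 ± 8.13 CPM). Neutrophil genes rose in 6 of 8 cases, 6 adjusted over the list alone (median 1.70, camera adjusted p = 0.000544, adjusted p = 0.331 with an estimated correlation). The neutrophil median was 2.33 without wild-type replicate 1, and that of B and plasma cells 3.52. Mmp9 was 6.93-fold higher. Complement genes rose in 18 of 21 cases and Cfb fell, 18 and 2 adjusted over the list alone (median 1.81, camera adjusted p = 4.92e-07, adjusted p = 0.331 with an estimated correlation). Cfi was 8.27-fold higher at 17.3 ± 5.56 CPM. Interferon response genes rose in 32 of 36 cases, 34 adjusted over the list alone (median 1.32, camera adjusted p = 8.6e-11, adjusted p = 0.331 with an estimated correlation). Ciita, uncertain as above, was 4.12-fold higher.

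Matrix and proliferation genes were higher at 12 weeks as well. Fibroblast and extracellular matrix genes rose in 37 of 40 cases, 38 adjusted over the list alone (median log2 fold change 1.37, camera adjusted p = 1.71e-15, adjusted p = 0.331 with an estimated correlation). Mmp7 rose 39.2-fold to 7.59 ± 1.54 CPM and the collagen cross-linking enzyme gene Lox 7.05-fold to 33.9 ± 10.2 CPM (edgeR adjusted p = 1.1e-06 and 4.1e-06). With few wild-type counts, the fold of Mmp7 was over 1.5 times larger without wild-type replicate 3. Transforming growth factor beta and Wnt signalling genes rose in 15 of 24 cases, 15 adjusted over the list alone (median 0.82, camera adjusted p = 7.95e-05, adjusted p = 0.331 with an estimated correlation). In the cell cycle list 27 of 30 genes rose, 27 adjusted over the list alone (median 1.64, camera adjusted p = 1.7e-10, adjusted p = 0.331 with an estimated correlation). Cdk1 was 5.23-fold higher at 5.12 ± 2.48 CPM. Immediate early and heat shock genes rose in 6 of 18 cases and Dusp1 fell, 6 and 1 adjusted over the list alone (median 0.39, camera adjusted p = 0.0414, adjusted p = 0.331 with an estimated correlation). Atf3 was 6.12-fold higher at 10.5 ± 2.64 CPM. The call of the immediate early and heat shock response list ended without knockout replicate 1 (camera adjusted p = 0.0598) or 6 (0.0721), without wild-type replicate 2 (0.059) or 6 (0.06) with genes of a mean CPM of at least 1 (0.0564) and with the replicate block (0.0602).

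Lower at 12 weeks were genes of the distal convoluted tubule, the collecting duct and mitochondria. Intercalated cell genes fell in 8 of 11 cases, 9 adjusted over the list alone (median log2 fold change -0.53, camera adjusted p = 3.29e-05, adjusted p = 0.331 with an estimated correlation). The pendrin gene Slc26a4 fell to 0.387 (59.7 ± 7.04 to 22.6 ± 2.82 CPM) and Insrr, uncertain as above, to 0.377 of wild type (edgeR adjusted p = 3.5e-07 and 5.8e-07). For principal cells 7 of 11 genes fell, 7 adjusted over the list alone (median -0.39, camera adjusted p = 0.0031, adjusted p = 0.331 with an estimated correlation). The aquaporin gene Aqp3 stood at 0.462 (92.6 ± 19.6 to 41.9 ± 9.2 CPM). Distal convoluted and connecting tubule genes fell in 8 of 10 cases, 8 adjusted over the list alone (median -0.47, camera adjusted p = 0.000252, adjusted p = 0.331 with an estimated correlation). Klhl3, a regulator of distal salt transport, stood at 0.590 and Pvalb at 0.433 of wild type. Respiratory chain genes fell in 27 of 30 cases, 29 adjusted over the list alone (median -0.36, camera adjusted p = 1.85e-09, adjusted p = 0.331 with an estimated correlation). Cox5b stood at 0.773 and Sdhc at 0.748 of wild type. Of 13 transcripts of the mitochondrial genome 10 fell, 11 adjusted over the list alone (median -0.60, camera adjusted p = 9.1e-06, adjusted p = 0.331 with an estimated correlation). mt-Nd2 stood at 0.579 of wild type (15600 ± 1330 to 8840 ± 1000 CPM). Their share of all counts was 13.7% ± 0.9 in wild type and 10.5% ± 1.1 in knockout. Genes with known sex-biased kidney expression fell in 7 of 15 cases while Abcc3 and Cyp4a14 rose, 8 and 2 adjusted over the list alone (median -0.52, camera adjusted p = 0.0179, adjusted p = 0.331 with an estimated correlation). Slc22a30 stood at 0.516 of wild type (345 ± 14.2 to 174 ± 32.5 CPM).

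Lipid genes gave weaker calls at 12 weeks. In the sterol synthesis and uptake list 8 of 26 genes fell and 2 rose, 8 and 2 adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 0.0382, adjusted p = 0.573 with an estimated correlation). Fatty acid oxidation and PPAR-alpha targets fell in 16 of 31 cases and rose in 5, 17 and 5 adjusted over the list alone; the median was -0.22 and the mean 0.01, and the test pointed down (camera adjusted p = 0.0382, adjusted p = 0.573 with an estimated correlation). Its gene with the smallest adjusted p, Angptl4, which encodes an inhibitor of lipoprotein lipase, rose 2.48-fold from 21 ± 5.75 to 51.1 ± 10.8 CPM (edgeR adjusted p = 0.00018). The call of sterol synthesis and uptake ended without knockout replicates 2, 5 or 6 (camera adjusted p = 0.0549, 0.0939 and 0.0589) or wild-type replicate 6 (0.0861), and without genes that overlap the opposite strand (0.158). The call of fatty acid oxidation and PPAR-alpha targets ended without knockout replicates 2, 5 or 6 (0.0542, 0.0609 and 0.0589) or wild-type replicates 3 or 6 (0.0601 and 0.0861), with genes of a mean CPM of at least 1 (0.0564), with the replicate block (0.0572), and without genes that overlap the opposite strand (0.237). With the replicate block the podocytes list passed (0.0316). The camera test called 24 of 38 lists at 12 weeks, 12 higher and 12 lower. Other splits of the 12 libraries gave a median of 16 and up to 27, so here too chance cannot be excluded for the number of lists. Of all tested genes 38.5% were called at 12 weeks. Near that share lay the sterol list (8 lower and 2 higher of 26), the renin-angiotensin list (4 and 1 of 12) and, with 6 higher and 1 lower of 18, the immediate early and heat shock list. The member counts of these lists therefore add little. Gipc1, Agt, Ccl28, Cfb and Cyp4a14 were named after their values were seen.

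Genes called at both durations changed mostly in the same direction. Of the genes higher in knockout, 2509 were shared, against 652 for independent lists (odds ratio 47.9), and of the lower genes 1595, against 412 (odds ratio 20.1), with a Fisher's exact p below the smallest number R represents in both cases. Lcn2, Spp1, Cxcl5, Mmp7, Slc34a3, Nepn and Lrp2 were among the shared genes. Of the 4116 genes called at both durations 12 changed in opposite directions. Across all 17286 genes the log2 fold changes of both durations correlated with Pearson's r = 0.784 and Spearman's rho = 0.727, and 76.6% had the same sign; over the 8004 genes called at either duration these were 0.824, 0.859 and 92.9%. Genes are not independent replicates, so no p is given for these correlations. For the same reason the Fisher's exact p does not measure the spread between samples. The comparisons share no library.

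**Figure D3:**
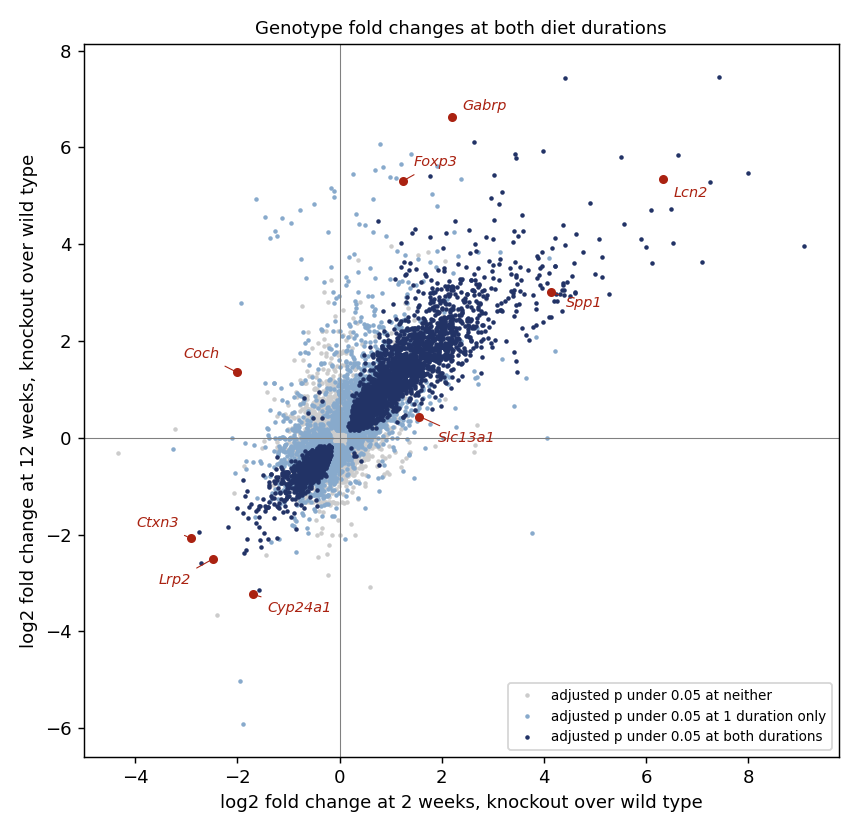
Fitted log2 fold change, knockout over wild type, of each tested gene at 2 weeks (horizontal axis) and 12 weeks (vertical axis), coloured by whether the gene passed at neither, 1 or both durations, with named genes in red. Lrp2 lies at -2.49 and -2.51, Lcn2 at 6.33 and 5.35, and Coch at -2.01 and 1.35.

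Few genes passed the test of whether the genotype effect itself differed between durations. Coch, a secreted extracellular protein gene, fell to 0.249 of wild type at 2 weeks (11 ± 1.89 to 2.67 ± 0.672 CPM) and stood at 4.69 ± 2.49 against 1.88 ± 1.51 CPM at 12 weeks, a difference that did not pass there (interaction log2 fold change 3.37, SE 0.53, edgeR adjusted p = 0.0029). Slc13a1 was 2.96-fold higher in knockout at 2 weeks and 1.36-fold higher at 12 weeks, with 662 ± 102 and 409 ± 77.1 CPM in knockout (interaction log2 fold change -1.13, SE 0.18, edgeR adjusted p = 0.0029). Foxp3 was 2.37-fold higher at 2 weeks and 39.7-fold higher at 12 weeks (interaction log2 fold change 4.10, SE 0.73, edgeR adjusted p = 0.0078), and the value was 4.77 without wild-type replicate 2 at 12 weeks. The glypican gene Gpc3 was 3.65-fold higher at 2 weeks and 1.79-fold higher at 12 weeks (interaction log2 fold change -1.03, SE 0.16, edgeR adjusted p = 0.0022). Igsf5, a tight junction protein gene, stood 1.21-fold higher at 2 weeks and at 0.803 of wild type at 12 weeks (interaction log2 fold change -0.59, SE 0.11, edgeR adjusted p = 0.014). Tnfrsf18, a costimulatory receptor gene of T cells, Camk4 and the antisense gene Slc13a2os had interaction log2 fold changes of 3.21, 3.14 and 2.96 (edgeR adjusted p = 0.00095, 0.0025 and 0.0022), with wild-type levels at 12 weeks of 0.247 ± 0.154, 0.282 ± 0.235 and 0.274 ± 0.253 CPM. Ppp4r4 and Acat3 passed narrowly (interaction log2 fold changes -0.89 and -0.80, SE 0.19 and 0.17, edgeR adjusted p = 0.045 each). Leaving out single libraries ended the call of Ppp4r4 in 18 of 24 fits and that of Acat3 in 19, with adjusted p up to 0.0986 and 0.114. The call of Ppp4r4 held without wild-type replicate 5 or knockout replicates 3 or 6 at 2 weeks and without wild-type replicate 1 or knockout replicates 1 or 3 at 12 weeks. That of Acat3 held without wild-type or knockout replicate 6 at 2 weeks and without wild-type replicate 4 or knockout replicates 1 or 3 at 12 weeks. Lrp2 had an interaction log2 fold change of -0.03 (SE 0.29, edgeR adjusted p = 0.99).

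In all, 30 of 17286 genes passed the interaction test, 20 with a larger and 10 with a smaller log2 fold change at 12 weeks, and 1835 had an unadjusted p under 0.05; DESeq2 called 154 genes, among them all 30. Without knockout replicate 3 at 12 weeks 56 genes passed. Of the 30 genes, 17 (56.7%) have exonic bases within a gene on the opposite strand, against 36.5% of all tested genes, and without such genes 9 passed. Foxp3, Tnfrsf18, Camk4, Slc13a2os, Acat3 and Gpc3 have such an overlap and are uncertain.

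For gene groups, at most 1 member of each list called in the interaction passed over all genes. For the injury list the median interaction log2 fold change was below 0 (-0.77, also with Sprr2f at its bound, camera adjusted p = 2.8e-09, adjusted p = 0.379 with an estimated correlation), with 0 of 27 genes called over all genes and 1 higher and 12 lower adjusted over the list alone. T and natural killer cells had a median of 0.77 (camera adjusted p = 1.1e-05, adjusted p = 0.611 with an estimated correlation), with Foxp3 the 1 of 20 genes called and 2 adjusted over the list alone; without knockout replicate 2 at 12 weeks the median was 0.36. The B and plasma cell list had a median of 1.76 with 0 of 22 genes called by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.000182, adjusted p = 0.676 with an estimated correlation). Without knockout replicate 2 at 12 weeks the median of the B and plasma cells list was 0.25 (camera adjusted p = 0.0433), so its size rested on that library. For proximal tubule transporters the median was -0.19, with Slc13a1 the 1 of 27 genes called and 1 adjusted over the list alone (camera adjusted p = 0.000339, adjusted p = 0.676 with an estimated correlation). No member was called in the endocytic list (median -0.22, 0 of 20 called, 0 adjusted over the list alone, camera adjusted p = 0.000173, adjusted p = 0.611 with an estimated correlation). The same held for the lysosome and autophagy list (median -0.15, 0 of 33 called, 0 adjusted over the list alone, camera adjusted p = 0.000796, adjusted p = 0.611 with an estimated correlation) and the sterol list (median -0.17, 0 of 26 called, 0 adjusted over the list alone, camera adjusted p = 0.00454, adjusted p = 0.676 with an estimated correlation). Principal cell genes had a median of -0.40 with 0 of 11 called and 2 lower adjusted over the list alone (camera adjusted p = 0.00756, adjusted p = 0.611 with an estimated correlation). Fatty acid oxidation genes had a median of 0.06, with Acot1 the 1 of 31 called and 1 adjusted over the list alone (camera adjusted p = 0.000339, adjusted p = 0.664 with an estimated correlation). Thick ascending limb genes had a median of 0.29 with 0 of 10 called and 2 adjusted over the list alone (camera adjusted p = 0.00195, adjusted p = 0.611 with an estimated correlation), and podocyte genes a median of 0.35 with 0 of 10 called and 3 adjusted over the list alone (camera adjusted p = 0.000394, adjusted p = 0.611 with an estimated correlation). Adipocyte genes had a median of 5.34 with 0 of 9 called and 6 adjusted over the list alone (camera adjusted p = 0.000339, adjusted p = 0.611 with an estimated correlation), and 4.16 to 6.39 with a library left out. The mean log2 CPM of the adipocytes list at 12 weeks was 3.28 to 5.79 in knockout replicates 1, 2, 4 and 5 but 0.118 and 0.179 in replicates 3 and 6, against -0.021 to 2.86 in wild type. Without replicate 3 or 6 the list passed at 12 weeks (camera adjusted p = 0.0363 and 0.0285). The inflammatory cytokines and chemokines list had a median of -0.15 with 0 of 33 called and 2 lower adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.676 with an estimated correlation). Its call ended without wild-type replicate 5 at 2 weeks (0.0502), wild-type replicates 1 or 3 at 12 weeks (0.122 and 0.0741) or knockout replicates 1 or 3 at 12 weeks (0.0636 and 0.0768). Without genes that overlap the opposite strand the principal cell and podocyte calls ended (camera adjusted p = 0.0503 and 0.0734), and the thick ascending limb list, with 4 members left, was not tested, which left 10 lists. Other splits gave a median of 14 and up to 27 lists, so chance cannot be excluded for the 13 calls of 38 lists. The rotation test of limma, fry, called 0 lists.

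Between 2 and 12 weeks of diet, many genes went from 0 counts to ready detection or the reverse, in both genotypes. Med10, a subunit gene of the Mediator complex, had 0 counts in all 12 libraries at 2 weeks and 21.1 ± 0.954 CPM in wild type and 24 ± 2.54 CPM in knockout at 12 weeks, at least 886-fold and at least 1030-fold higher. Pdcd2 was at least 690-fold and 632-fold higher and the pseudouridine synthase gene Pus3 at least 527-fold and 551-fold higher at 12 weeks in wild type and knockout. The metallothionein gene Mt2 stood at 0.019 ± 0.0296 and 11.2 ± 2.35 CPM in wild type and at 0.137 ± 0.17 and 26.4 ± 2.82 CPM in knockout. The mitochondrial transfer RNA gene mt-Tl2 was at least 179-fold lower at 12 weeks in wild type and at least 93.6-fold lower in knockout, and Il4, the interleukin 4 gene, at least 45.9-fold and 70.1-fold lower. Itgb2l went from 24.8 ± 3.58 to 0.0155 ± 0.0381 CPM in wild type and from 23.4 ± 5.29 to 0.0116 ± 0.0285 CPM in knockout, where 1 library of each genotype held all its counts at 12 weeks, and mt-Tc from 46 ± 9.97 to 0.0621 ± 0.0762 CPM and from 32 ± 18.1 to 0.0255 ± 0.0396 CPM. Ccdc27 was at least 83-fold lower at 12 weeks in wild type and stood at 2.48 ± 0.539 and 0.0214 ± 0.0334 CPM in knockout, and Ighg3 stood at 0.0448 ± 0.0511 and 62.9 ± 140 CPM in knockout. Of the latter, replicate 2 held 348 CPM of Ighg3 and the others 0.246 to 23.9 CPM. Lrp2 did not pass in either genotype (log2 fold change -0.10, SE 0.21, edgeR adjusted p = 0.76 in wild type and -0.13, SE 0.21, 0.68 in knockout).

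The duration test called 5263 of 17286 genes in wild type, 2727 higher and 2536 lower at 12 weeks, and 5840 in knockout, 3058 higher and 2782 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Groups did not overlap for 2758 genes in wild type and 2467 in knockout, against a chance share of 0.216%. In knockout Spp1 fell to 0.337 of its level at 2 weeks and Lcn2 to 0.517, while Ciita rose 2.21-fold (edgeR adjusted p = 3.2e-07, 0.0031 and 1.1e-06). All were chosen outside the naming rule for duration, and Ciita is uncertain for its overlap with an opposite-strand gene. Without genes that overlap the opposite strand 2694 and 3103 of 10983 genes were called. Med10, Pdcd2, Pus3, Mt2 and Itgb2l overlap genes on the opposite strand, and the mice, sequencing run and counting of each duration cannot be separated in this design: all libraries of a duration list the genes in 1 order and those of the other duration in another, so a difference in handling coincides with duration. The genotype comparisons are within a duration and do not cross it.

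Within knockout libraries, the Lrp2 RNA that remained was set against the mean log2 CPM of the injury and transporter lists, which made 4 relations over 6 libraries each. At 12 weeks, transporter RNA was higher where Lrp2 was higher (Pearson's r = 0.82, exact permutation p = 0.00833, adjusted p = 0.0333; Spearman's rho = 0.83, exact permutation p = 0.0583, adjusted p = 0.181), and r was 0.76 without the 2 libraries farthest in Lrp2. For transporters at 2 weeks r was 0.79 (exact permutation p = 0.0597, adjusted p = 0.119) and rho 0.71 (exact permutation p = 0.136, adjusted p = 0.181), with r = 0.42 without the 2 farthest libraries. For injury genes at 2 weeks r was -0.67 (exact permutation p = 0.158, adjusted p = 0.211) and rho -0.71 (exact permutation p = 0.136, adjusted p = 0.181), with r = -0.63 without the 2 farthest. Injury genes at 12 weeks gave r = 0.32 (exact permutation p = 0.597, adjusted p = 0.597) and rho = 0.26 (exact permutation p = 0.658, adjusted p = 0.658), and r = -0.89 without the 2 farthest, so that relation rests on those libraries. The tests were two-sided, and 1 of the 4 relations passed by r and none by rho after Benjamini-Hochberg adjustment. Lrp2 and the transporters are both RNA of the proximal tubule, so a share of tubule RNA that differs between libraries would move them together. That was not tested. At 12 weeks knockout replicate 2 held the lowest Lrp2 (186 CPM) and transporter score (7.43) and the highest macrophage and dendritic cell (5.93) and B and plasma cell (6.53) scores. Replicate 3 held the highest Lrp2 (390 CPM) and transporter score (8.06) and the lowest macrophage and dendritic cell score (4.89).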

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

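The tests of cell share and dilution for transporters, of the genes higher and lower at 12 weeks and of overlap among interaction genes were chosen after their result was seen; the others were written before. A library stood far from the other 5 of its group in 38 of 628 tests over the named genes, lists and library measures (the gap to the nearest library over the range of the group exceeded Dixon's 95% value), and chance flags about 1 in 20 groups.

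Lrp2 itself was lowest in knockout replicate 2 at 12 weeks, at 186 CPM against 307 to 390 CPM. In the same library Sprr2f stood at 0.242 CPM (others 0.798 to 1.12), Ppp4r4 at 4.11 CPM (5.07 to 5.58) and the T and natural killer cell list at a mean log2 CPM of 3.24 (1.04 to 1.81). Knockout replicate 2 at 2 weeks had 15.1% of its counts in 10 genes (others 10 to 11.1%) and 10.1% on mitochondrially encoded genes (5.6 to 6.9%), with mt-Nd2 at 9670 CPM (3520 to 4480), the mitochondrially encoded list at a mean log2 CPM of 10.2 (8.86 to 9.29), Cox5b at 107 CPM (174 to 227) and Cyp24a1 at 3.96 CPM (15 to 30.3). In knockout replicate 5 at 2 weeks Sdhc stood at 202 CPM (235 to 253), Amn at 72.1 CPM (99.4 to 115), Cidec at 0 CPM (0.623 to 1.03) and the adipocyte list at a mean log2 CPM of 0.236 (1.91 to 2.79). Other knockout libraries at 2 weeks were apart in Spp1 (4590 CPM in replicate 6, others 8370 to 10100), F5 (1.35 CPM in replicate 3, 2.35 to 2.97), mt-Tl2 (7.84 CPM in replicate 1, 1.76 to 3.04) and the thick ascending limb list (7.06 in replicate 4, 6.86 to 6.93). Itgb2l had 0.0697 CPM in knockout replicate 1 at 12 weeks and 0 CPM in the others.

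Wild-type replicate 1 at 12 weeks had the highest Ighm of its group (187 CPM, others 7.79 to 20.4), Ctxn3 (14.7 CPM, 4.29 to 6.79), B and plasma cell list (3.27, 0.114 to 1.28) and adipocyte list (2.86, -0.0208 to 0.768), and the lowest Usp2 (52.9 CPM, 74.4 to 91.1). Wild-type replicate 6 at 12 weeks stood apart in Wnt11 (0.168 CPM, 1.4 to 3.96), Cox5b (275 CPM, 241 to 253) and Aldh1a2 (2.35 CPM, 4.26 to 5.37), replicate 4 in Itgb2l (0.0933 CPM, others 0) and Fdft1 (14.5 CPM, 19.5 to 21.4), and replicate 3 in mt-Nd2 (13000 CPM, 15500 to 16900). At 2 weeks, wild-type replicate 1 had 34.1 M counts (others 15.6 to 20.7), Saa1 at 0.0278 CPM (others 0) and Acy3 at 1410 CPM (1880 to 2170). Replicate 3 had Egf at 1530 CPM (1710 to 1830), Cox5b at 172 CPM (239 to 265) and Ighg3 at 0.104 CPM (0 to 0.0278), replicate 4 had Plin4 at 10.3 CPM (2.97 to 4.03) and replicate 5 had Ccl5 at 0.335 CPM (0.877 to 1.35).

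The genotype effect differed between durations, by the edgeR interaction test, for Coch (3.37), Foxp3 (4.10), Tnfrsf18 (3.21), Camk4 (3.14), Slc13a2os (2.96), Slc13a1 (-1.13), Gpc3 (-1.03), Ppp4r4 (-0.89), Acat3 (-0.80) and Igsf5 (-0.59), given as interaction log2 fold changes. By the camera test at the preset correlation, but for none with an estimated correlation (adjusted p from 0.379 to 0.676) and for none by fry, it differed for the lists of injury (adjusted p = 2.8e-09), T and natural killer cells (1.1e-05), endocytosis (0.00017), B and plasma cells (0.00018), transporters, fatty acid oxidation and adipocytes (0.00034 each), podocytes (0.00039), lysosome and autophagy (8e-04), thick ascending limb (0.002), sterol synthesis (0.0045), principal cells (0.0076) and cytokines (0.016).

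Transporter RNA of the proximal tubule was lower in knockout kidneys at both durations, and 3 other explanations were set against a change within the tubule. A smaller share of proximal tubule RNA would raise markers of other nephron segments, but the highest upper quartile of the distal convoluted tubule and intercalated cell lists was -0.28. The other distal lists had upper quartiles above 0 at 1 duration (thick ascending limb 0.13 at 12 weeks, principal cells 0.10 at 2 weeks) with medians of 0.01, so segments moved apart and a smaller proximal share alone does not account for the lower lists. Dilution of all resident RNA by infiltrating cells would lower podocyte genes alike. But the lower quartile of the podocyte list lay above the upper quartile of the transporter list by at least 0.23. At 2 weeks the podocyte list hardly moved (median -0.05). At 12 weeks it leaned higher (6 of 10 genes higher, median 0.44), so it is no neutral reference there. Under RLE or upper-quartile scaling the list median was at most -0.46, so the choice of TMM over these 2 scalings does not explain it. All 3 scalings centred the fold changes of all genes alike at 2 weeks (median -0.005 with TMM, -0.018 with RLE and 0.012 with upper-quartile factors). An offset that they share was not tested and stays open. A lower level per tubule cell may explain the pattern, and loss of several nephron segments together stays open. A smaller proximal share together with dilution was not tested and stays open too.

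Many genes were at or near 0 counts at 1 duration in both genotypes, which may come from counting without regard to strand at 2 weeks and with it at 12 weeks. Of the 55 genes at least 32-fold higher at 12 weeks 85.5% had at least 50% of their exonic bases covered by exons of an opposite-strand gene, against 0.3% of the 15667 genes that differed less than 2-fold, which such a difference predicts. Antisense genes inside an opposite-strand gene had a median log2 fold change of -0.57 with quartiles of -4.23 and 0.19 over 343 genes. Protein-coding genes without such overlap had a median of -0.01 with quartiles of -0.18 and 0.18 over 9317 genes. The antisense median fell between the limits set in advance for and against a counting difference, so it does not decide. Their lower quartile lay far below that of the protein-coding genes, which a counting difference predicts. Genes called in the interaction overlapped opposite-strand genes more often (17 of 30, two-sided Fisher's exact p = 0.0347), so part of these calls may share this source. For the antisense genes as a set, the median does not tell counting and an effect of diet or age apart, though the lower quartile leans to counting. For the genes higher at 12 weeks, the overlap argues against diet or age as the whole cause. So do the 0 counts of Med10, Pdcd2 and Pus3 in all 12 libraries at 2 weeks. Of the 246 genes at least 32-fold lower at 12 weeks 62.2% had at least 50% of their exonic bases inside an opposite-strand gene, against 8.2% of those that differed less than 2-fold, which argues the same for this set. For the genes outside such overlap a strand difference gives no account. Il4 and mt-Tl2, with 0 counts in both genotypes at 12 weeks, are among them. Diet, age and other handling that coincides with duration stay open for these genes, untested.

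B and plasma cell RNA was higher in knockout kidneys at 12 weeks, with Ighm highest in replicate 2. Without that library the list median was 1.66, so this library alone is not the cause of the 12-week difference. Lymphoid tissue in the samples or infiltration of the kidney may explain the pattern, and neither was tested.

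Among the splits of the libraries that were tried, the true grouping gave the most called genes at 2 weeks (5467, highest other split 585) and 12 weeks (6653, 3703). The same held in both with 1 direction (4104, 0) and between durations in wild type (5263, 980) and knockout (5840, 2085). This argues against chance for these counts but does not exclude it, with 100 splits for genotype and 60 for duration. Other splits mix the compared groups, so a real difference widens the spread within each part. The size of the gap is therefore partly built in. For the interaction (30, 0) such mixing also removes the effects that this test must keep, so the splits cannot decide there. Chance cannot be excluded for the number of lists called at 2 weeks (21, highest other 27), at 12 weeks (24, 27) and in the interaction (13, 27). As many lists came from 14 and 12 of 100 splits and 35 of 60 splits. The other splits gave a median of 14, 16 and 14 lists but of 0 called genes in these comparisons. A camera call at the preset correlation therefore carries little weight by itself.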

How the results depend on the processing

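Removal of genes that overlap the opposite strand, and left-out libraries for the correlation of fold changes and the shared calls, were chosen after seeing the data; the other alternatives were planned. No called result changed direction. With an added minimum log2 fold change of 1, which calls fewer genes by construction, 1620, 1993, 19, 1514 and 1734 genes passed at 2 weeks, at 12 weeks, in the interaction and by duration in wild type and knockout. Without genes that overlap the opposite strand, which leaves 10983 genes to test, 4420 passed at 12 weeks, 9 in the interaction, and 2694 and 3103 by duration. DESeq2 called 154 genes in the interaction, and the cause was not tested.

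Leaving out each library in turn gave 4826 to 6063 genes at 2 weeks, 5515 to 6961 at 12 weeks and 22 to 56 in the interaction, where 56 came without knockout replicate 3 at 12 weeks and the cause was not tested. It gave 4525 to 5031 genes by duration in wild type and 5107 to 5978 in knockout, 21 to 22, 22 to 26 and 12 to 18 lists, and a correlation of fold changes from 0.762 to 0.791. That correlation was 0.794 with DESeq2, 0.808 with a mean of at least 1 CPM, 0.796 with the replicate block and 0.803 without overlapping genes.

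With an estimated correlation camera called 1 list at 2 weeks, 0 at 12 weeks and 0 in the interaction, and fry called 28, 28 and 0 lists; the cause was not tested. With the replicate block 5103, 5950, 21, 4921 and 5387 genes passed, and 23 lists at 12 weeks, where 2 calls ended and 1 was gained. With no filter the share of higher genes among duration calls in wild type was 40.4% against 51.8%.

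Among named genes 2924 results under alternatives other than a left-out library kept direction and side of the threshold, 19 lost the threshold and 2 uncalled Lrp2 values near 0 moved to 0 or past it; with a library left out these were 4150, 78 and 8. For lists 567 held, 82 lost and 18 passed the threshold, and 11 changed direction; with a library left out these were 1661, 18, 60 and 85. All lists that changed direction were uncalled. The neutrophils list (a mean of at least 1 CPM) and the thick ascending limb list (no overlapping genes) had 4 members left and were not tested there. Calls of named genes lost include Ighm at 2 weeks (all 24 libraries, adjusted p = 0.347), Ppp4r4 and Acat3 in the interaction (replicate block, 0.15 and 0.131), and Tef and Cidec at 12 weeks (no filter, 0.0601 and 0.0584). The cause was not tested. The alternative with sex as a covariate was not run, since all libraries fell in 1 class. Depth limits genes near 1 CPM.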

Other observations

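Beyond the comparisons above, some members of lists that did not pass at 1 or both durations rose or fell in knockout kidneys. Aldh1a2, a retinoic acid synthesizing enzyme gene, rose 16.8-fold at 2 weeks (2.17 ± 0.351 to 35.2 ± 10.7 CPM) and 9.12-fold at 12 weeks (4.59 ± 1.17 to 41 ± 10.5 CPM; edgeR adjusted p = 7.1e-09 and 4.8e-07). Stra6, a retinol transporter gene, rose 18.5-fold and 11.7-fold (edgeR adjusted p = 1.3e-08 and 1.1e-06). Their list, vitamin and carrier-protein handling, did not pass (camera adjusted p = 0.613 and 0.344). The calcium channel gene Trpv5 rose 2.37-fold and 1.34-fold, and Trpv6 rose at 2 weeks from 1.75 ± 0.505 to 5.13 ± 0.855 CPM and at 12 weeks 2.88-fold. Ctss, a lysosomal protease gene of antigen-presenting cells, rose 5.94-fold and 5.51-fold, Apoe 3.06-fold and 3.18-fold, and the scavenger receptor gene Msr1 8.20-fold and 4.04-fold. The vascular endothelial growth factor receptor gene Kdr fell to 0.718 and 0.579 of wild type, and Ehd3 to 0.694 and 0.739. Sod2 fell to 0.762 and 0.735, and Me1 to 0.741 and 0.668. At 12 weeks Ephx1 was 1.63-fold higher, Usp2 (uncertain for its overlap with another gene) stood at 0.608 and Tef at 0.631 of wild type.

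In the adipocyte list at 12 weeks, Plin4 was 4.04-fold higher (2.04 ± 0.962 to 8.05 ± 6.73 CPM, edgeR adjusted p = 0.016) and Cidec 18.1-fold (0.416 ± 0.551 to 7.39 ± 8.52 CPM, edgeR adjusted p = 0.026). The Cidec call ended without knockout replicate 4 or wild-type replicates 5 or 6 (highest adjusted p = 0.0575), and its log2 fold change of 4.18 was 3.43 without knockout replicate 4 and 5.15 without wild-type replicate 1.

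At 2 weeks 17 lists did not pass the camera test. Given as genes higher and lower of those tested, the counts adjusted over the list alone, the median log2 fold change and the camera adjusted p, endocytosis had 0 and 4 of 20 (0 and 2, -0.06, 0.231) and vitamin D and mineral handling 3 and 5 of 15 (3 and 8, -0.21, 0.231). Vitamin and carrier-protein handling had 5 and 4 of 20 (6 and 4, -0.05, 0.613; mean 0.51, test up) and the renin-angiotensin system 1 and 4 of 12 (1 and 4, -0.14, 0.122). Sterol synthesis had 4 and 5 of 26 (4 and 5, -0.10, 0.493; the mean was above 0), and cholesterol efflux and LXR targets 7 and 1 of 14 (7 and 1, 0.26, 0.0504). The cholesterol efflux and LXR targets list passed in 7 of 12 fits with a library left out (lowest adjusted p = 0.0334) and under RLE scaling (0.0465). Lysosome and autophagy had 10 and 4 of 33 (10 and 5, -0.01, 0.613; mean and test up), NRF2 targets 6 and 7 of 24 (6 and 7, -0.14, 0.275; mean above 0) and endoplasmic reticulum stress 6 and 2 of 22 (6 and 2, 0.05, 0.231). Principal cells had 0 and 4 of 11 (0 and 4, 0.01, 0.122; mean and test down), podocytes 0 and 1 of 10 (0 and 1, -0.05, 0.506), endothelial cells 0 and 4 of 14 (0 and 4, -0.03, 0.144) and adipocytes 0 and 1 of 9 (0 and 1, -0.73, 0.527; median 0.05 without wild-type replicate 4). Blood and red cells had 1 and 1 of 8 (1 and 1, -0.36, 0.356; mean above 0, median -1.11 without knockout replicate 3), liver 2 and 1 of 7 (2 and 2, 0.10, 0.613), the circadian clock 1 and 7 of 20 (1 and 7, -0.20, 0.11) and sex-biased genes 1 and 5 of 15 (1 and 5, -0.25, 0.128).

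At 12 weeks 14 lists did not pass, in the same order of values. Vitamin D and mineral handling had 3 and 5 of 15 (4 and 5, -0.26, 0.241), vitamin and carrier-protein handling 8 and 5 of 20 (8 and 5, 0.18, 0.344) and lipogenesis 1 and 6 of 18 (2 and 6, 0.01, 0.49; test down). Cholesterol efflux had 8 and 3 of 14 (8 and 4, 0.43, 0.211), lysosome and autophagy 5 and 13 of 33 (5 and 13, -0.12, 0.183; mean above 0), NRF2 targets 6 and 7 of 24 (6 and 9, -0.10, 0.467; mean above 0) and endoplasmic reticulum stress 5 and 2 of 22 (4 and 2, 0.12, 0.138). The thick ascending limb had 2 and 2 of 10 (2 and 2, 0.01, 0.636; mean and test down), podocytes 6 and 0 of 10 (6 and 0, 0.44, 0.0663), endothelial cells 1 and 4 of 14 (1 and 4, -0.11, 0.185) and adipocytes 6 and 0 of 9 (8 and 1, 4.18, 0.112; median 5.63 without wild-type replicate 1 and 3.43 without knockout replicate 4). Blood and red cells had 1 and 1 of 8 (1 and 1, 0.72, 0.686), liver 2 and 0 of 7 (2 and 0, 0.06, 0.404) and the circadian clock 1 and 6 of 20 (1 and 5, -0.27, 0.185).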
